A study of Homo sapiens with 6 samples.

How the data were processed

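miRNA sequencing libraries came from exosomes collected by centrifugation of medium conditioned by HCT116 cells at passage 16 to 19, with RNA taken up in Trizol and 100 ng of total RNA per library, per the labels' protocols. The labels name an Illumina TruSeq RNA kit, and do not say how small RNAs were selected. Per the submitters' processing notes, Trimmomatic, FastQC and featureCounts were used and the genome build was GRCh37.p5. Their versions, the aligner, the treatment of reads with several positions and the miRNA annotation are not given in the sources used here. The deposited files hold whole-number counts per mature miRNA entry for each library, not normalised. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

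Groups were taken from the sample titles, with 3 libraries each. The deposited file names give the opposite group in 6 of 6 libraries, and no value was used to decide between them. The deposited counts also count some reads at more than one place: miR-199a-3p, which has 2 loci, held 2.00 times the counts of miR-199b-3p in the first titled untreated library (1374 against 687) although their mature sequences are the same, and the ratio was 2 to 2.002 in the others. Levels of entries with several loci, such as miR-7-5p with 3 and miR-7641 with 2, can be inflated for that reason, alike in both groups, and such entries are not independent.

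Entries were kept by edgeR's filterByExpr with its default minimum count of 10, which left 195 of 2575 entries for testing and 2380 untested. Tested entries held at least 99.6% of the counts of each library. Counts were normalised by TMM (factors 0.776 to 1.19) and tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts relative to the TMM-scaled library size, with mean and SD over 3 libraries. The edgeR test gives no standard error. Standard errors (SE) of its log2 fold changes were derived as the absolute log2 fold change over the square root of F. The biological coefficient of variation was 12.9% and the prior degrees of freedom 4.84. Depth sets the floor: 3 counts correspond to 7.19 to 15.0 CPM depending on the library, and floors and intervals cover counting error only, since the libraries carry no molecular identifiers in the sources used here.

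17 lists of miRNAs were fixed before the data were examined: the let-7 family, the miR-17~92 cluster and paralogues, the miR-200 family, gut epithelial, inflammation and NF-kappaB responsive, colorectal oncogenic and p53-linked miRNAs, the miR-15/16, miR-23/27/24, miR-29 and miR-30, miR-10/99/100/125, miR-320 and miR-181 families, the 14q32 cluster, blood-cell markers, other-tissue markers and entries overlapping other RNA classes. Some miRNAs stand in more than one list. Lists with at least 3 tested members were tested by camera with an inter-gene correlation of 0.01, by camera with an estimated correlation and by fry. Composition was compared by exact permutation of the 6 libraries, two-sided, for which 0.1 is the smallest p.

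The rule for named entries was also fixed before the data were examined. It takes up to 12 entries each way with the largest change among those past the threshold, with non-overlapping groups and a mean of at least 10 CPM. It adds the 10 most abundant entries, miR-149, and in each list the 2 most abundant and the 2 smallest p. miR-183-5p, miR-320c and miR-122-5p fall outside the rule, as do the further entries that the closing observations name, and were chosen after their values were seen. Host genes come from GENCODE release 29, in which 195 of 195 tested entries matched a miRNA gene; no coordinates are given because its build is not the submitters'.

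Alternatives were the size factors of DESeq2, library size alone, upper-quartile scaling, no filter, a filter of 10 CPM in 3 libraries, DESeq2's Wald test, limma-voom, the replicate number as a block, copies of a miRNA summed, the fragment list left out, and each replicate left out in turn. After the data were seen, leaving out miR-7641 with the fragment list and scaling on other-tissue markers were added. Scripts were tested on simulated data with 2575 entries, of which 200 were changed and 202 tested. For the comparison of the titled groups, 87.0% of 23 tested entries changed by 2-fold and 100% of 19 changed by 4-fold were called, 7.14% of calls were false, and 0 calls were made among 195 tested entries with no change simulated. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.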

Results

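Small RNA sequencing was carried out on exosomes, the small vesicles that cells release, from HCT116, a human colorectal cancer line. The cells had been co-cultured for 6 h with enterotoxigenic Bacteroides fragilis (ETBF), a toxin-producing gut anaerobe linked to colitis and colorectal tumours, or kept with bacterial medium alone. The multiplicity of infection was 500. There were 6 libraries, 3 titled untreated and 3 titled ETBF. The series' title places the work in intestinal inflammation and colorectal carcinogenesis, and the comparison asks which exosomal miRNAs differ after contact with the bacterium. The sample titles and the names of the deposited files contradict each other in 6 of 6 libraries: each file whose sample is titled untreated is named for ETBF, and the reverse. Groups here follow the titles. If the file names are right, every direction below is the opposite of the one written, so that counts and shares of higher entries become those of lower entries, while the sizes of differences, errors and p-values stay as they are.

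The deposited tables list 2575 mature miRNA entries, of which 717 had a count in any library. Libraries were shallow, with totals from 200207 to 417321 counts. Mean totals were 287525 for the titled untreated libraries and 296576 for the titled ETBF libraries (exact permutation test, two-sided, p = 0.9, n = 3 per group; 0.1 is the smallest p this design allows). Between 417 and 482 entries had at least 1 count in a library. Few miRNAs held most of the counts: the 10 most abundant entries took 76.1% ± 0.723 of the titled untreated libraries and 79.2% ± 3.96 of the titled ETBF libraries (SD, n = 3, exact permutation p = 0.4). That difference of 3.08 percentage points was -0.0422 without the most abundant entry, miR-148a-3p.

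miR-148a-3p alone made up 32.6% ± 6.00 of the counts in the titled untreated libraries and 42.3% ± 9.0 in the titled ETBF libraries (SD, n = 3, exact permutation p = 0.3). miR-21-5p, a widely expressed oncogenic miRNA, made up 9.29% ± 0.344 and 8.79% ± 2.15 (SD, n = 3, exact permutation p = 0.7). The entry miR-7641 took 17.1% ± 6.43 of the titled untreated counts and 0.450% ± 0.0761 of the titled ETBF counts (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.52 over the measures of library composition). Spearman correlations of log2 CPM across entries, which are not independent replicates, ran from 0.982 to 0.985 among titled untreated libraries, from 0.976 to 0.981 among titled ETBF libraries and from 0.944 to 0.972 between the groups. The first principal component held 74.6% of the variance and separated the titled groups. Titled ETBF replicate 1 scored 3.54 on it, against 6.17 and 6.25 for replicates 2 and 3. Replicate counts differed by far more than sampling noise in each pair within a group (chi-square over degrees of freedom 10.04 to 104). No library was therefore treated as deposited more than once, though this does not show that the libraries come from separate RNA samples.

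miR-149, the miRNA the published study of this series is known to concern, was 6.03-fold higher in the libraries titled ETBF. Its level was 37.4 ± 7.13 CPM in the titled untreated libraries and 234.9 ± 37.4 CPM in the titled ETBF libraries (SD, n = 3), a log2 fold change of 2.59 with a standard error of 0.23 (edgeR, adjusted p = 8.18e-05). The 3 titled untreated libraries held 6, 15 and 13 counts and the 3 titled ETBF libraries held 57, 56 and 84, so the groups did not overlap. The entry names no arm, so miR-149-3p and miR-149-5p cannot be separated in it. In GENCODE release 29 the MIR149 gene lies in an intron of GPC1, a heparan sulphate proteoglycan gene. The title of the published study, known from outside these files, speaks of ETBF inhibiting exosome-packaged miR-149-3p, which is the direction the file names would give and the opposite of the one the sample titles give.

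Across the 195 entries with enough counts to test, 28 differed between the titled groups at an adjusted p under 0.05, with 21 higher and 7 lower in the libraries titled ETBF. Among the largest differences were falls in miR-7641, miR-6087 and miR-1246, whose sequences overlap abundant structural RNAs. That overlap was not tested here. miR-7641 is not in the fixed list of entries overlapping other RNA classes, and was grouped with the others after its values were seen. miR-7641 was 36.3-fold lower (log2 fold change -5.18, SE 0.28, adjusted p = 2.39e-06) and miR-6087 was 24.4-fold lower (log2 fold change -4.61, SE 0.25, adjusted p = 2.39e-06). miR-1246, which derives largely from the spliceosomal RNA U2, went from 3890 ± 182.5 to 971.8 ± 355.6 CPM (SD, n = 3), 4.0-fold lower.

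Among abundant miRNAs, miR-7-5p, which represses the EGF receptor, went from 17058 ± 1187 to 75153 ± 5094 CPM (SD, n = 3), 4.41-fold higher in the libraries titled ETBF (log2 fold change 2.14, SE 0.12, adjusted p = 2.62e-06). miR-100-5p, a repressor of mTOR, went from 7622 ± 1573 to 26722 ± 5403 CPM, 3.50-fold higher (SE 0.19 on the log2 scale, adjusted p = 0.000259). miR-186-5p was 2.20-fold higher, from 1083 ± 106.3 to 2387 ± 374.7 CPM (adjusted p = 0.000367). miR-7-5p is encoded by 3 loci, of which MIR7-1 lies in HNRNPK and MIR7-3 in an intron of MIR7-3HG in GENCODE release 29. MIR100 lies in an intron of MIR100HG and MIR186 in an intron of ZRANB2.

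Less abundant miRNAs were also higher in the libraries titled ETBF. miR-9-3p, one arm of a neurone-enriched miRNA, held 3, 6 and 0 counts in the titled untreated libraries and 27, 15 and 54 in the titled ETBF libraries, with a log2 fold change of 3.40 (SE 0.62, adjusted p = 0.00705). The titled untreated libraries lie near the floor of 3 counts, so single libraries set the fitted size of that difference. It was 2.73 without titled untreated replicate 3 and 4.15 without titled untreated replicate 2. The log2 fold changes of miR-95-3p, miR-203b-3p, miR-139-5p, miR-132-3p and miR-548o-3p were 1.54, 1.49, 1.48, 1.45 and 1.43 (SE 0.33, 0.34, 0.28, 0.40 and 0.25). That of miR-95-3p was 2.23 without titled untreated replicate 2. miR-203b-3p passed in 17 and miR-132-3p in 14 of 19 settings tried, the main one included. miR-345-5p had a log2 fold change of 1.12 (SE 0.31) and passed in 11 of the 18 settings that tested it, with adjusted p up to 0.154. MIR139 lies in an intron of PDE2A. Smaller falls in the libraries titled ETBF were those of miR-889-3p at -0.99 (SE 0.26), miR-375 at -0.61 (SE 0.17), miR-127-3p at -0.58 (SE 0.12) and miR-99a-5p at -0.39 (SE 0.09). Only miR-127-3p of these passed in all 19 settings; miR-889-3p passed in 8, miR-375 in 12 and miR-99a-5p in 13, with adjusted p up to 0.151, 0.158 and 0.187.

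Of the 28 entries, 12 of the higher and 3 of the lower differed by at least 2-fold. All 28 had groups of libraries that did not overlap, as did 76 of the 195 tested entries, where chance gives 10%. At an unadjusted p under 0.05 there were 66 entries. The median log2 fold change of tested entries was -0.03 and the median standard error 0.18. Among the most abundant miRNAs, miR-148a-3p (0.51, SE 0.31), miR-151a-3p (1.05, SE 0.35), let-7f-5p (0.33, SE 0.11), miR-26a-5p (0.15, SE 0.11) and miR-21-5p (-0.03, SE 0.12) did not pass, with adjusted p of 0.290, 0.0749, 0.0746, 0.413 and 0.851. The count of calls depended on single libraries: it was 59 without titled ETBF replicate 1, 17 without titled ETBF replicate 3 and 17 without titled untreated replicate 3, with 26, 16 and 15 of the 28 kept. Without titled ETBF replicate 1, miR-148a-3p reached a log2 fold change of 0.73 (adjusted p = 0.00153, against 0.00153 to 0.787 over the alternatives tried). Testing without the low-count filter gave 51 calls. The share of calls that were higher, 75%, was 85.7% with upper-quartile scaling and 91.8% when libraries were scaled on markers of other tissues. It was 59.4% without the fragment list and 64.4% without titled ETBF replicate 1. These are shares of lower calls if the file names are right.

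**Figure D1:**
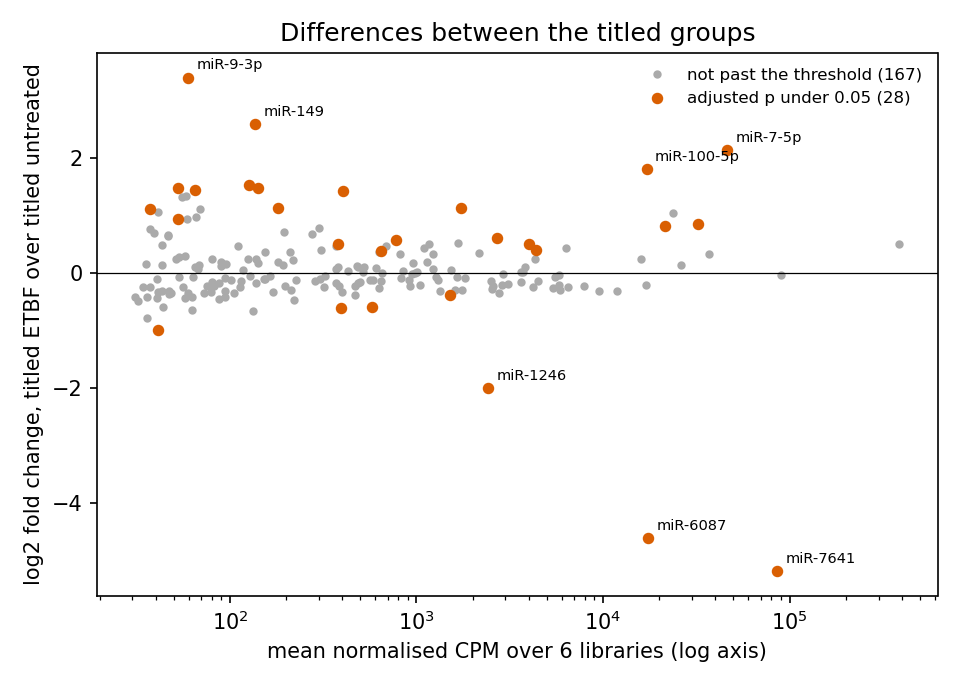
Log2 fold change of the libraries titled ETBF over those titled untreated (vertical axis) against mean normalised CPM over the 6 libraries on a log axis, with 1 point per tested entry. The 28 orange points passed an adjusted p of 0.05, and miR-7641, miR-6087 and miR-1246 lie far below the 167 others that did not.

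**Figure D2:**
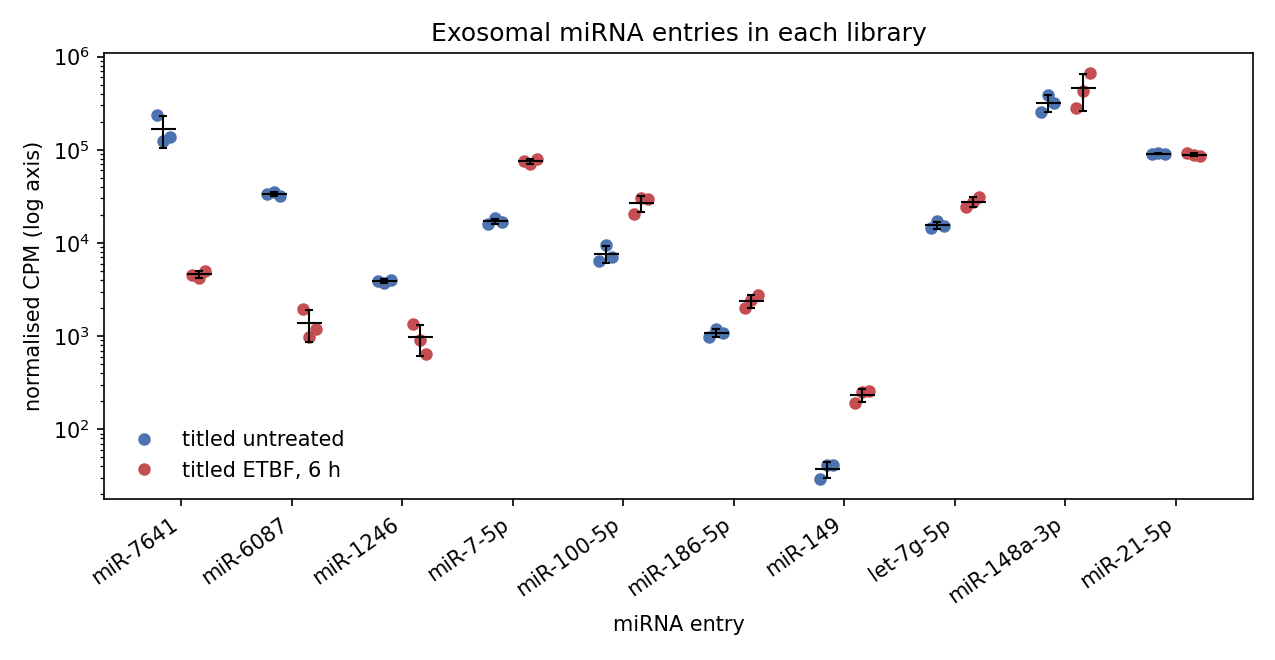
Normalised CPM on a log axis for 10 miRNA entries in each library, with 3 libraries titled untreated (blue) and 3 titled ETBF (red); black lines are means and bars are SD. The groups of libraries do not overlap for the 8 entries on the left and do overlap for miR-148a-3p and miR-21-5p.

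The let-7 family, which restrains RAS and other growth genes, had 11 tested members, of which 2 were higher in the libraries titled ETBF, none was lower, and 9 did not pass. let-7i-5p went from 23000 ± 3198 to 41581 ± 7447 CPM (SD, n = 3, log2 fold change 0.85, SE 0.16) and let-7g-5p from 15542 ± 1387 to 27560 ± 3249 CPM (0.83, SE 0.12), with adjusted p of 0.00885 and 0.00249. MIRLET7G lies in an intron of WDR82. Adjusted over the list alone the count was 2. In the miR-10, miR-99/100 and miR-125 families, 2 of 9 were higher, miR-100-5p and miR-10a-5p (0.40, SE 0.11, past the threshold in 12 of 19 settings), and 1 was lower, miR-99a-5p, with 2 and 1 adjusted over the list alone. The median of that list was -0.13 while its mean was 0.15 and its test pointed up. miR-320a (0.38, SE 0.09) and miR-320b (1.13, SE 0.19) were the 2 of 3 tested miR-320 members that passed, and all 3 passed adjusted over the list alone. miR-320b passed in 19 of 19 settings and miR-320a in 12, with adjusted p up to 0.462. miR-320c, named after its values were seen, had 1.33 with a standard error of 0.56 (adjusted p = 0.134).

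The colorectal oncogenic list had 12 tested members, of which 3 were higher: miR-95-3p, miR-96-5p (0.51, SE 0.14) and miR-183-5p (0.51, SE 0.14), the last named after its values were seen. miR-96-5p passed in 13 and miR-183-5p in 15 of 19 settings. Adjusted over the list alone there were 4, with miR-182-5p added (0.44, SE 0.15, adjusted p over all entries 0.0757). Of 11 tested inflammation and NF-kappaB responsive miRNAs, 2 were higher, miR-132-3p and miR-9-3p, and 9 did not pass, with 2 adjusted over the list alone. Of 6 tested gut epithelial miRNAs, miR-375 was lower and 5 did not pass; 4 were lower adjusted over the list alone. The members added were miR-192-5p (-0.31, SE 0.09), miR-194-5p (-0.29, SE 0.09) and miR-203a (-0.31, SE 0.11), whose adjusted p over all entries were 0.0587, 0.0666 and 0.0838. The other-tissue markers other than miR-9 had a weighted mean log2 fold change of -0.21 ± 0.03 (SE). That SE treats the markers as independent, though they come from the same 6 libraries and share the error of scaling. When libraries were scaled on those markers, miR-375 had -0.41 (adjusted p = 0.158), and miR-192-5p, miR-194-5p and miR-203a had -0.10, -0.08 and -0.10. The 14q32 imprinted cluster had 13 tested members, of which miR-127-3p and miR-889-3p were lower and 11 did not pass, with 2 adjusted over the list alone; 11 of the 13 had a negative log2 fold change and the median was -0.33. The call of miR-889-3p held in 8 of 19 settings.

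No member passed over all entries in 8 lists. The miR-200 family, which keeps epithelial identity, had 7 tested members with a median of -0.03; miR-200a-3p (-0.06, SE 0.09) and miR-200b-3p (-0.03, SE 0.09) turned positive with upper-quartile scaling and when scaled on other-tissue markers. The p53-linked list had 10 tested members with a median of -0.27, and the miR-181 family had 3 with a median of -0.14, of which miR-181a-5p (-0.29, SE 0.09) was lower adjusted over the list alone. The miR-17~92 cluster and its paralogues had 9 tested members with a median of 0.01 and a mean of -0.01, and the test pointed down. The miR-15/16 family had 4 with a median of -0.12. The miR-23/27/24 clusters had 6 with a median of -0.12 and a mean of 0.02, the test pointing down. The miR-29 and miR-30 families had 9 with a median of -0.07 and a mean of 0.00312, again with the test pointing down. Apart from miR-181a-5p, none of the members of these lists or of the blood-cell list passed adjusted over the list alone.

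Some markers of other tissues were abundant in both groups. miR-1, a muscle miRNA, stood at 18228 ± 881.1 CPM in the titled untreated libraries and 15856 ± 1631 CPM in the titled ETBF libraries, and miR-122-5p, a liver miRNA named after its values were seen, at 5892 ± 591.6 and 4932 ± 128.9 CPM (SD, n = 3). Their log2 fold changes were -0.20 (SE 0.11) and -0.26 (SE 0.10), with edgeR adjusted p of 0.237 and 0.0911. The value of miR-1 was 0.00672 when libraries were scaled on these markers. As miR-1 is itself the most abundant of them, a value that small follows from the scaling. Of 16 tested other-tissue markers, miR-9-3p was higher and 15 did not pass, with 1 adjusted over the list alone. The median of the list was -0.20 while its mean was 0.06, and 13 of its 16 members were negative. Of 5 tested blood-cell markers, 0 passed, 2 were positive and 3 negative, and the median was -0.06. In the list of entries overlapping other RNA classes, miR-6087 and miR-1246 were the only 2 tested members and both were lower, also adjusted over the list alone. The share of counts in that list was 3.84% ± 0.0211 in the titled untreated libraries and 0.250% ± 0.136 in the titled ETBF libraries (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.52).

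By camera with its preset correlation, 0 of the 16 lists with at least 3 tested members differed from the other entries at an adjusted p under 0.05, and 1 did at an unadjusted p under 0.05, the 14q32 cluster (p = 0.0457, adjusted p = 0.395; p = 0.146 with an estimated correlation). With an estimated correlation 0 lists passed as well. The smallest adjusted p by camera was 0.395, shared by the 14q32, gut epithelial and miR-320 lists. fry, which asks whether members move on balance one way and does not compare them with other entries, passed 8 of 16 lists. The 4 pointing up were the let-7, inflammation, colorectal oncogenic and miR-320 lists, and the 4 pointing down were the gut epithelial, p53-linked, miR-181 and 14q32 lists.

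**Figure D3:**
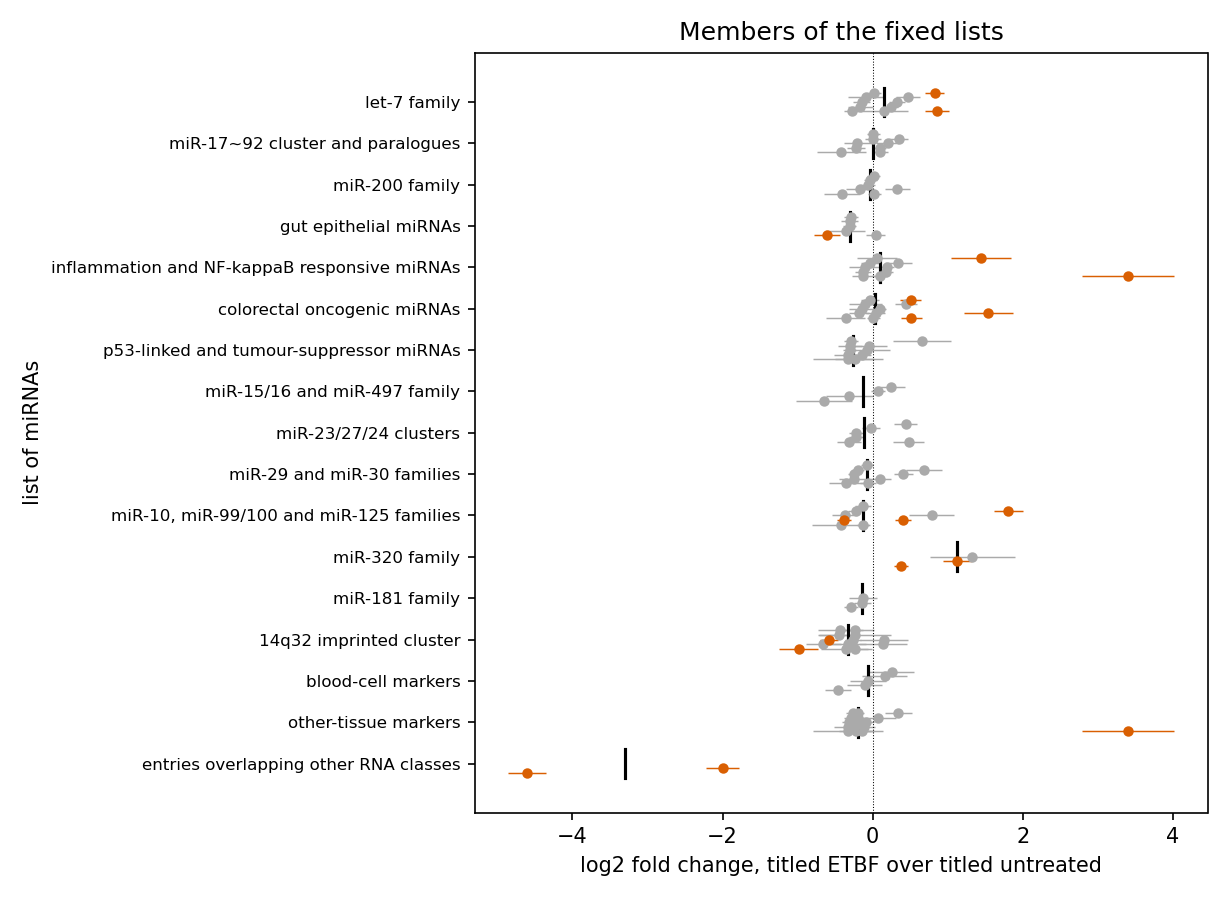
Log2 fold change of the libraries titled ETBF over those titled untreated for each tested member of the 17 fixed lists; horizontal bars are standard errors, black ticks are medians and orange points passed an adjusted p of 0.05. The 2 tested entries overlapping other RNA classes lie at -4.61 and -2.0, and miR-9-3p lies at 3.40 among other-tissue markers whose median is -0.20.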

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

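Of the settings here, leaving out miR-7641 with the fragment list and scaling on other-tissue markers were chosen after the result was seen, and the rest were planned. miR-149 passed in all 19 settings, the main one included, with log2 fold changes from 2.49 to 2.79 and adjusted p up to 0.000614. All 28 calls kept their sign in each setting that tested them, but not their side of the threshold: miR-889-3p passed in 8 of 19 settings, miR-345-5p in 11 of 18, miR-320a, miR-10a-5p and miR-375 in 12, miR-96-5p and miR-99a-5p in 13, miR-132-3p in 14, miR-183-5p in 15 and miR-203b-3p in 17 of 19. The other 15 named calls passed in each setting that tested them. The main 28 calls (21 higher, 7 lower) became 51 (39 and 12) with no filter, 49 (45 and 4) when scaled on other-tissue markers, 42 (36 and 6) with upper-quartile scaling, 34 (30 and 4) without miR-7641 and the fragment list, 32 (19 and 13) without the fragment list and 21 (17 and 4) with library size only. DESeq2 gave 29, limma-voom 25 and the 10 CPM filter 26. Leaving out single replicates gave 17 to 59 calls, 12 to 38 higher and 4 to 21 lower. The higher share by the titles (the lower share by the file names) was 75% in the main setting. It was 85.7% with upper-quartile scaling, 59.4% without the fragment list and 88.2% without miR-7641 and that list. Scaling on other-tissue markers shifted the log2 fold changes of entries by a median of 0.20 and gave a share of 91.8%. Without titled ETBF replicate 1 the share was 64.4%. The cause of these moves in the share was not tested.

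The replicate block gave 38 calls, of which 26 were among the main 28. Same-numbered libraries deviated together with r of 0.18, 0.10 and 0.05, against -0.16 to 0.07 for pairs with different numbers. Each titled untreated library correlated best with the titled ETBF library of its number, but titled ETBF replicate 3 correlated best with titled untreated replicate 2. The labels do not state a pairing, and correlations this small cannot settle whether there was 1.

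No list passed in the main camera test; fry passed 8, and the 10 CPM filter gave 1, the fragment list, which then had 4 tested members (adjusted p = 0.000106). Rank agreement within groups exceeded that between groups by 0.0293, and by 0.0203 with the 10 CPM filter. The composition difference of 3.08 points was -0.0422 without the most abundant entry and ranged from 1.24 to 5.18 when single replicates were left out; the difference in total counts ranged from -51322 to 49750, with -34608 without titled untreated replicate 1.

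Signs turned only for entries and lists that did not pass. With upper-quartile scaling miR-200a-3p, miR-200b-3p and miR-21-5p had log2 fold changes of 0.00878, 0.0360 and 0.0325. Without miR-7641 and the fragment list miR-200b-3p and miR-21-5p had 0.0186 and 0.0161. Scaled on other-tissue markers, miR-1, miR-181b-5p, miR-199a-3p, miR-200a-3p, miR-200b-3p, miR-21-5p and miR-486-5p had 0.00672, 0.0604, 0.0108, 0.149, 0.181, 0.179 and 0.0918. Of these, miR-1 and miR-199a-3p are among the markers scaled on, so their small values follow from the scaling. Without titled ETBF replicate 2, miR-200a-3p, miR-200b-3p, miR-21-5p and miR-486-5p had 7.27e-05, 0.0270, 0.0149 and 0.00483. miR-486-5p had 0.0718 and miR-223-3p -0.103 without titled ETBF replicate 3, and miR-16-5p had -0.0388 without titled untreated replicate 3. The miR-17~92 list turned with fry (adjusted p = 0.591) and without titled ETBF replicate 3 (0.965), and the miR-10, miR-99/100 and miR-125 list without titled untreated replicate 3 (0.743) and titled ETBF replicate 3 (0.965). Over single replicates left out, log2 fold changes ranged up to 0.148 for miR-16-5p and 0.424 for miR-223-3p, and down to -0.140, -0.109, -0.0911 and -0.438 for miR-200a-3p, miR-200b-3p, miR-21-5p and miR-486-5p; the lowest adjusted p were 0.876 for the miR-17~92 list and 0.687 for the miR-10, miR-99/100 and miR-125 list. Depth limits how many entries could be tested, 195 of the 717 with a count.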

Other observations

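The tests of abundant entries, of sequencing depth, of other fragment entries, of ribosomal RNA fragments, of a single foreign source, of the miR-9 arms and of exchanged titles were chosen after the result was seen, and the test of other splits was set before it. Of 27 miRNAs with both arms tested, 10 had a log2 ratio of the 3p to the 5p arm that did not overlap between the titled groups. Chance gives 10%, but 76 of the 195 single entries did not overlap either, a similar share, so arm ratios do not stand out. None passed adjustment over the 27, and none could, since 0.1 is the smallest p. For miR-9 the ratio went from -7.07 ± 2.17 to -3.75 ± 0.588 (SD, n = 3; exact permutation p = 0.1, the smallest possible; adjusted p = 0.27), but titled untreated replicate 3 held 0 counts of miR-9-3p, so its ratio is set by the pseudocount of 0.5 and the size is uncertain. miR-9-3p rose by the titles while miR-9-5p had a log2 fold change of 0.34 (SE 0.18, adjusted p = 0.210). The ratio of miR-374a was -0.83 ± 0.191 in the titled untreated and 0.17 ± 0.386 in the titled ETBF libraries (SD, n = 3). That of miR-10a was -6.61 ± 0.0516 and -7.68 ± 1.01. Both were named after their values were seen. miR-10a-3p averaged 31.1 CPM and did not itself pass (log2 fold change -0.42, SE 0.39, edgeR adjusted p = 0.491).

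Titled ETBF replicate 1 lies closest to the other group on the first principal component. Without it, 59 entries passed, 26 of the main 28 and 33 others. Among the 33, chosen after their values were seen, miR-151a-3p (1.35, SE 0.15, adjusted p = 2.13e-08) and miR-99b-3p (1.04, SE 0.18) were higher in that fit. In it, miR-205-5p (-0.47, SE 0.12) and miR-125a-5p (-0.63, SE 0.15) were lower. With all libraries their edgeR adjusted p were 0.0749, 0.0939, 0.0601 and 0.147, so none passed. Leaving out the library closest to the other group favours more calls. That library held miR-151a-3p at 15592 CPM, within the titled untreated range of 10688 to 18001 CPM. It also lay within the titled untreated range for miR-99b-3p and miR-125a-5p. For miR-205-5p it did not, at 2735 CPM against 2975 to 3410 CPM. As the 33 further calls did not pass with all libraries, they cannot be taken as differences between the titled groups.

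The entries miR-7641, miR-6087 and miR-1246 overlap structural RNAs, though miR-7641 is outside the fixed fragment list. They were far lower in the libraries titled ETBF, which library depth cannot account for, since the ratio of mean totals was 1.03. Pooled, the 21 other fragment entries showed no excess in the titled untreated libraries. Their ratio, titled ETBF over titled untreated, was 1.03 (77 against 75 counts, 95% interval 0.737 to 1.43, counting error only). So few counts cannot speak for each class of RNA, and the pool includes miR-3648 and miR-3687. An excess of ribosomal RNA fragments stays open: miR-3648 and miR-3687, named after their counts were seen, held 4 against 9 counts. Their ratio was 0.444 (95% interval 0.10 to 1.59). Such an excess alone would not cover miR-1246, which derives largely from the spliceosomal RNA U2 and was 4.0-fold lower. With TMM scaling, 25 of 25 other calls remained when these entries and the fragment list were left out. TMM already trims entries with extreme ratios, so that test could hardly show that the other calls depend on them. With library size alone, 17 of the 28 main calls were kept. A change in vesicle content after the bacterium, which the design could give, was not tested.

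Muscle, liver, stroma and endothelium markers shared a ratio between the titled groups. The weighted mean log2 fold change of 14 markers was -0.21 ± 0.03 (SE), and 13 of them were negative. That SE treats the markers as independent, though they share the error of scaling. Library size alone shifted tested entries by a median of -0.07 and upper-quartile scaling by 0.07. Of random sets of other entries matched on level, 0 of 10000 varied as little as the markers. One source of foreign RNA present in all libraries may account for this, for example medium or reagents, but miR-199a-3p and miR-199b-3p share reads, and the p53-linked list, which holds some of the same miRNAs, varied almost as little (percentile 0.05 of 2000 sets). The 14q32 list (2.05) and miR-200 family (3.15) were low too, so a small spread is not special to foreign markers. The miR-9 arms had been left out after their values were seen; with all 16 markers the spread lay at percentile 5.25 of 10000 sets, and the explanation stays open. miR-9-3p and miR-9-5p lay 5.86 and 3.15 standard errors from the mean of the other markers, which restates why they were set apart and decides nothing.

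The titled direction stays open. File names carry the opposite group in 6 of 6 libraries, and no library is out of place alone. Exchanged titles and exchanged file names therefore cannot be told apart from the counts alone. The title of the published study, known from outside these files, speaks of ETBF inhibiting an exosome-packaged arm of miR-149. With miR-149 higher in the libraries titled ETBF, that title goes with the file names and against the sample titles. It is not part of the data, and the miR-149 entry names no arm. If the titles are exchanged, miR-149, miR-7-5p and miR-100-5p may be lower and miR-7641 and miR-6087 higher after ETBF. For the 28 calls, 1 of the 10 splits of the 6 libraries, the real one, gave as many; the highest of the others gave 0, and 10 splits are too few for a share under 0.05.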
